A study of Saccharomyces cerevisiae with 13 samples.

How the data were processed

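The 13 libraries are paired-end maps of mononucleosomes from W303 yeast grown to an OD600 of 0.4 to 0.6 and digested with MNase and ExoIII until about 80% of the ladder was mononucleosomes, per the labels' protocols. Each deposited file gives a signal for every base pair of 16 nuclear chromosomes and of mitochondrial DNA. The submitters' processing notes name CASAVA, TopHat2 and SAMtools without versions, and the genome build is not given in the sources used here. In every file the deposited signal is a whole multiple of 1 step per library (99.9997% to 100% of nonzero values within 0.1 of a whole number), and the step makes the mean close to 1, so fragments per position could be recovered. That each value counts fragment midpoints is inferred from the values, not stated. In 5 libraries (matched set 2 and the ume6 deletion with the inactive fusion) values above about 50 are absent and positions high elsewhere hold 0, mostly in the rDNA. The files of set 3 end 1 position earlier per chromosome, and the longer ones were shortened to match.

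Values were divided by each library's nuclear mean without the rDNA. The plan drawn up before the data were examined foresaw sites at matches of the Ume6 motif. No genome sequence was at hand, so its stated fallback was used: for each gene of 2 lists fixed beforehand, early meiotic (28 genes) and metabolic and other (22 genes), the centre was the lowest point of the mean of the 3 WT libraries, smoothed with a Gaussian of SD 20 bp, in the 600 bp upstream of the ORF. The 50 members gave 49 sites, because HOP1 and SPO22 share 1. Some sites are also the trough of a neighbour outside the lists and are named here by the list gene alone. Among the genes named below these are CAR2 (with DIF1), MEK1 (TFB6), MND1 (GTS1), SMK1 (NHP6A), SPO13 (ARD1), POT1 (BNR1) and MEI5 (VPS30). A change there cannot be assigned to 1 of the 2 genes. The motif scan, the stricter and looser motifs, motifs inside ORFs, the control motifs, the correction for GC content and the distance of windows to motifs were not run for the same reason. Gene names and neighbours came from a gene table of assembly R64. Because the files name no build, its coordinates are not printed and positions are those of the files. In the ume6 and isw2 deletions without a fusion, 99.5% of positions of the UME6 ORF and 99.7% of the ISW2 ORF as placed by this table held 0.

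A site's value was log2(mean signal within 25 bp of the centre + 0.1) minus log2(mean within 500 bp + 0.1), kept where the local mean was at least 0.25. The distance measure was that to the nearest maximum within 300 bp with a height of at least 0.5 of the local mean. Windows were 100 bp with a mean of at least 0.1, as log2(value + 0.1), without the rDNA and 1000 bp around UME6, ISW2 and CHD1: 115647 of 120142 were tested. Troughs were chosen in WT libraries, so a comparison against WT starts from positions where WT is low by choice.

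Pairing comes from the labels, which name matched WT libraries. It was checked over the 115647 windows in the 4 groups with a library in sets 1 and 3: the deviations from the group means correlated between groups with r from 0.203 to 0.773 over 6 pairs of groups. Matched set was therefore a block in all fits. Per-library means were compared by exact permutation tests, two-sided, of the active fusion within matched sets (240 permutations), 7 tests with Benjamini-Hochberg adjustment. Sites and windows were tested with limma 3.58.1 (R 4.3.3) with Benjamini-Hochberg adjustment at 0.05. The active and inactive fusion came from a fit with terms for active fusion, inactive fusion, ume6 deletion, isw2 deletion and set (6 residual degrees of freedom). The ume6 deletion, and the fusion in each background, came from a fit with 8 groups and set (3 residual degrees of freedom), which pools the spread so that lone libraries are assumed to vary like the others. Gene lists were set against all 4855 promoters with camera. The plan called for edgeR in place of limma where files hold whole counts. The deposited values are scaled signal, so limma stayed the main test and edgeR 4.0.16 on recovered fragments was added. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 did the rest.

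The fits were tested on simulated fragment counts for the 115647 windows with 200 changed ones. For the active fusion 59.7% of 1.5-fold changes and 100% of 2-fold and 4-fold changes were recovered with 13 false calls. For the ume6 deletion 16.4%, 71.6% and 100% were recovered with 10 false calls. The simulation used 1 dispersion for all windows, no effect of matched set and no uneven chromosomes. These rates may therefore not carry over to the real libraries.

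Named list genes follow a rule set before the data were examined: up to 12 rises and 8 falls past the threshold with the same direction in all 5 matched differences, plus INO1, CAR1, IME2, SPO13, HOP1, SPO11, REC8, RIM4, REC104 and POT1. For the ume6 deletion they are up to 8 in each direction, and for windows the 5 largest in each direction over 500 bp from a list site. The window counts of the inactive fusion, of active against inactive and of the fusion in each background, the largest promoters outside the lists, the held-out use of set 2, the regions near URA3 and ADH1, the scaling within chromosomes and the comparison of ume6 with isw2 were chosen after the data were examined. Window, half-width, pseudocount, filter, smoothing, block, quantile normalization and leaving out each library were varied, with effects in the closing section. For list-site counts, quantile normalization was applied to the 49 sites alone. It gives every library the same distribution over them, so rises at some sites are offset by falls at others. Mitochondrial DNA was not analysed here.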

Results

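Nucleosomes were mapped in W303 budding yeast in log growth by paired-end sequencing of mononucleosome-sized DNA left after digestion with micrococcal nuclease and exonuclease III. Some strains carry an engineered remodeler that joins Chd1, an ATPase that slides nucleosomes, to Ume6, a DNA-binding repressor of early meiotic and some metabolic genes. The comparisons ask what this fusion does to nucleosomes, with an ATPase-dead variant, called the inactive fusion here, as its control. The 13 libraries fall into 8 groups: wild type (WT, 3 libraries), WT with the active fusion (2), ume6 deletion (2) and ume6 deletion with the active fusion (2). The other 4 groups have 1 library each: ume6 deletion with the inactive fusion, isw2 deletion, isw2 deletion with the active fusion and isw2 deletion with the inactive fusion. Isw2 is a remodeler that Ume6 is known to recruit. The labels name a matched WT library for each strain, which gives 3 matched sets of 5, 4 and 4 libraries. They do not say whether libraries of a group came from separate cultures, so the spread between them may be technical.

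Depth ran from 16.8 to 55.7 M fragments per library, with a median of 35.2 M. WT held 19.1, 27.2 and 40.6 M, WT with the active fusion 25.9 and 38.3 M, the ume6 deletion 35.2 and 41.6 M, and the ume6 deletion with the active fusion 25.5 and 40.0 M. The ume6 deletion with the inactive fusion held 55.7 M, the isw2 deletion 16.8 M, and the isw2 deletion with the active or inactive fusion 29.6 or 49.4 M.

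The deleted genes and the fusion showed in the signal of the libraries labelled with them. Over the UME6 ORF, signal relative to the nuclear mean was 0.0213 ± 0.0219 (SD, n = 5) in ume6-deletion libraries and 1.12 ± 0.157 (SD, n = 8) in the others. Over the ISW2 ORF it was 0.00175 ± 0.000715 (SD, n = 3) in isw2-deletion libraries and 1.04 ± 0.0547 (SD, n = 10) in the others. CHD1, part of which the fusion carries, had 1.77 ± 0.216 (SD, n = 7) with a fusion, and values from 1.03 to 1.21 in the 6 libraries without one. In the ume6-deletion libraries with a fusion, the 3′ part of UME6 that encodes its DNA-binding domain held 0.357 ± 0.178 (SD, n = 3), and the rest of the ORF 0.00173 ± 0.00128 (SD, n = 3).

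With the active fusion, nucleosome signal rose in the promoter troughs of a group of meiotic genes. At HOP2, needed for pairing of homologous chromosomes, it rose 3.01-fold (log2 1.59 ± 0.18 SE, trough at VII 435529). At REC104, needed for meiotic DNA breaks, it rose 2.46-fold (log2 1.30 ± 0.16 SE, VIII 412850), and at SAE3, a helper of the meiotic recombinase, 2.28-fold (log2 1.19 ± 0.15 SE, VIII 262654). MEI4 (log2 0.86 ± 0.21), the trough shared by HOP1 and SPO22 (0.79 ± 0.16), IME2 (0.75 ± 0.17), DMC1 (0.74 ± 0.16) and MSH4 (0.64 ± 0.17) also rose. In all, 8 of 27 early meiotic sites rose, 0 fell and 19 did not pass. Of 22 sites of metabolic and other genes with known Ume6 control, 3 rose and 0 fell: CAR2, an enzyme of arginine breakdown (2.08-fold, log2 1.06 ± 0.16, XII 1012375), PHR1, the DNA photolyase (log2 0.79 ± 0.16), and HSP82, an Hsp90 chaperone (log2 0.52 ± 0.14). Each of the 11 was higher in 5 of 5 matched differences between a fusion library and its parent. Limma's adjusted p for them lay between 1.44e-05 and 0.0103. In this fit the inactive fusion has its own term, so the 5 libraries with the active fusion are set against the 6 with no fusion. Of those 6, WT replicate 2 has no weight. The 11 are the count adjusted over the list alone, and 10 of the 11 passed when adjusted over all 4855 promoters. Of the genes fixed beforehand, 7 did not pass: INO1 (log2 0.35), REC8 (0.34), CAR1 (0.095), POT1 (0.088), SPO11 (-0.0050), SPO13 (-0.070) and RIM4 (-0.43). Limma's adjusted p for them lay between 0.116 and 0.975.

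Per library, the mean over the early meiotic sites was -2.35 ± 0.13 (log2 relative to the 500 bp on each side, SD, n = 5) with the active fusion and -2.64 ± 0.16 (SD, n = 8) without it. The difference within matched sets was 0.32 (exact permutation test, two-sided, 240 permutations, p = 0.00417, the smallest they can give, Benjamini-Hochberg adjusted p = 0.0146 over 7 tests). Over all 49 sites the difference was 0.22 (exact permutation p = 0.00417, adjusted 0.0146). These permutations share the choice of centres, troughs of the WT libraries, which favours the real labels. With centres on the trough of all 13 libraries the differences were 0.21 (early meiotic, exact permutation p = 0.0125), 0.12 (all 49, p = 0.025) and 0.013 (metabolic and other, p = 0.671), unadjusted. Back on the WT centres, the difference over all 49 was 0.091 with a pseudocount of 0.5 and 0.44 with 0.01. With WT centres the matched differences over the 49 were 0.26 and 0.29 in WT, 0.16 and 0.30 in the ume6 deletion and 0.14 in the isw2 deletion. For the metabolic and other sites the difference was 0.10 (exact permutation p = 0.1, adjusted 0.175). The nearest nucleosome maximum lay 91.3 ± 3.81 bp (SD, n = 5) from the trough with the active fusion and 99.2 ± 7.68 bp (SD, n = 8) without it, a difference of -7.88 bp within sets that failed the correction (exact permutation p = 0.0292, adjusted 0.0681), and of -6.25 bp (p = 0.158) with the trough of all 13 libraries. The matched differences in distance went both ways in WT, 5.41 and -5.86 bp, and were -8.04 and -16.2 bp in the ume6 deletion and -13.0 bp in the isw2 deletion. Against all promoters, the early meiotic sites shifted upward (median log2 0.17, mean 0.32, camera adjusted p = 4.22e-04), with adjusted p = 0.0828 when the correlation was estimated. Quantile normalization gave 7 rising and 6 falling sites. It was applied to the 49 sites alone, which offsets rises with falls, so its falls cannot be told apart from the method. Centres placed on the trough of all 13 libraries gave 5 rising. For the 49 sites, exact permutation p was 0.075 with a centre of 75 bp on each side, and 0.0625, the smallest the other 8 libraries allow, without the 5 ume6-deletion libraries. The fitted change turned negative at MSH4 (-0.090), IME2 (-0.11) and HSP82 (-0.15) when the trough was sought within 1000 bp, and at CAR2 (-0.012) with 75 bp.

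**Figure D1:**
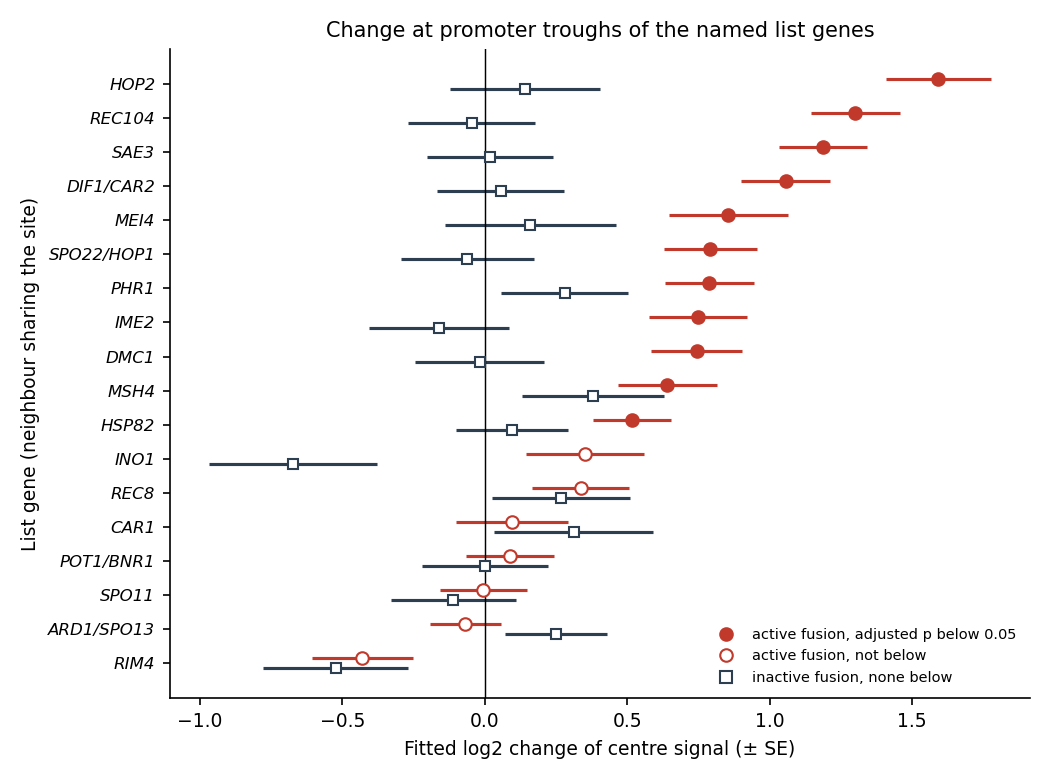
Fitted log2 change of centre signal (horizontal axis, with SE) at the promoter troughs of the named list genes (vertical axis). Circles are the active fusion (5 libraries, against the 6 with no fusion) and squares the inactive fusion (2 libraries). Filled circles passed limma's adjusted threshold of 0.05, from HOP2 at 1.59 to HSP82 at 0.52 (MSH4, IME2 and HSP82 turn negative with 1000 bp upstream and CAR2 with a 75 bp centre), and no inactive value passed.

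**Figure D2:**
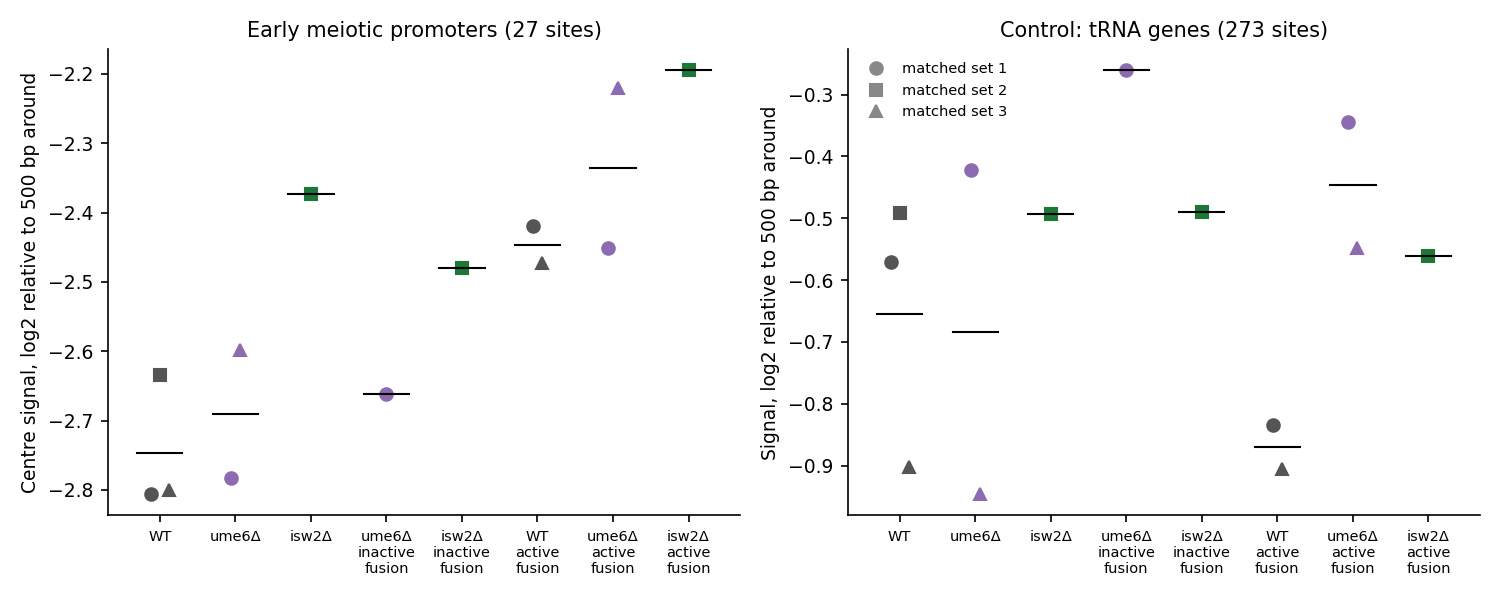
Mean centre signal per library, log2 relative to the 500 bp on each side, over 27 early meiotic sites (left) and 273 tRNA genes (right), by group, with points for libraries, shapes for matched sets and bars for group means. Within matched sets the active fusion differed from the rest by 0.32 on the left and by -0.021 on the right. Sites on the left are troughs of WT and those on the right are not.

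At places chosen as controls no difference passed. They sit at fixed positions and not at troughs of WT, so they cannot show the bias from the choice of centres. At 273 tRNA genes the difference within sets was -0.021 (exact permutation p = 0.85, adjusted 0.908). At 5955 ORF starts it was 0.0063 (exact permutation p = 0.854, adjusted 0.908), and at 132 ribosomal protein promoters it was -0.024 (exact permutation p = 0.908, adjusted 0.908). The ribosomal protein value is log2 signal without the local mean taken off. Over the WT troughs of all promoters, which share the choice of centres, the difference was 0.053. At the tRNA genes the matched differences between fusion and parent were -0.26 and -0.0044 in WT, 0.078 and 0.40 in the ume6 deletion and -0.068 in the isw2 deletion.

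With the inactive fusion, fitted changes were small at the 4 list promoters with the largest gains of the active one. HOP2 had a fitted log2 change of 0.14 ± 0.26 SE, REC104 of -0.047 ± 0.22, SAE3 of 0.016 ± 0.22 and CAR2 of 0.055 ± 0.22, over 2 libraries. These are terms of the fit, not differences from the parents. Site values in ume6, then isw2, against the parent were -2.72 against -2.41 and -2.23 against -2.68 at SAE3. They were -2.10 against -1.86 and -2.64 against -2.60 at CAR2, -2.72 against -2.82 and -2.78 against -3.21 at HOP2. At REC104 they were -2.92 against -2.87 and -2.14 against -2.26. By limma 0 of 49 sites passed, 2 lay under an unadjusted 0.05, and edgeR also gave 0. Tested directly, the active fusion exceeded the inactive at 8 sites and lay below it at 0, with limma's adjusted p over the list at or under 0.0268. Adjusted over all promoters 4 passed, 3 of them early meiotic. Of the sites called for the active fusion, MSH4, PHR1, MEI4 and HSP82 did not pass this direct test (limma's adjusted p over the list from 0.157 to 0.663). The inactive fusion had log2 changes of 0.38, 0.28, 0.16 and 0.096 there. The 8 were HOP2 (log2 1.45 ± 0.26 SE), REC104 (1.35 ± 0.22), SAE3 (1.17 ± 0.22), INO1, which makes inositol phosphate (1.02 ± 0.30, from 0.35 with the active and -0.67 with the inactive fusion, neither past the threshold), CAR2 (1.00 ± 0.22), IME2 (0.91 ± 0.25), HOP1 with SPO22 (0.85 ± 0.23) and DMC1 (0.76 ± 0.23), 6 of them on the early meiotic list. Against all promoters the early meiotic sites lay higher with the active than with the inactive fusion (camera adjusted p = 2.65e-04, and adjusted p = 0.077 with an estimated correlation). Ribosomal protein promoters shifted upward with the inactive fusion (median log2 0.11, camera adjusted p = 0.00561), with adjusted p = 0.712 with an estimated correlation. The count rests on both inactive libraries: it was 3 without the isw2-deletion one and 0 without the ume6-deletion one, and the inactive fusion itself gave 1 lower site without the 5 ume6-deletion libraries. Quantile normalization over the 49 sites alone gave 4 higher and 2 lower sites. Trough centres of all 13 libraries or a pseudocount of 0.01 gave 3 higher, and a 10 bp centre or leaving out the ume6-deletion libraries gave 4. The 2 inactive libraries are the deepest (49.4 and 55.7 M) and are among the 5 with high positions set to 0. The ume6-deletion one held 1.94% of fragments in the rDNA, against 7.04% to 10.3% in the rest of its set. The check of pairing did not cover it. In that background the contrast cannot be told apart from how the library was processed.

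Of all 4855 promoter troughs, list sites included, signal rose with the active fusion at 169 and fell at 4, and 64 of the gains exceeded 2-fold. These centres are troughs of WT, which favours rises over falls. The trough of all 13 libraries was tried for the list sites alone. Windows, not chosen this way, gave 1466 gains and 586 losses. The following genes were chosen after their values were seen, as the largest gains outside the lists that were higher in all 5 matched differences. That condition held for 162 of the 169. HSC82, the constitutive Hsp90, rose 7.86-fold (log2 2.97 ± 0.19 SE, trough at XIII 632064), the trough of ATP7 and PUT3, the activator of proline use, 6.80-fold (log2 2.77 ± 0.24, XI 408393), and YOR019W 5.19-fold (log2 2.37 ± 0.14, XV 368086). CNB1, a calcineurin subunit, and GAL10, an enzyme of galactose use, each rose by log2 2.01 (± 0.16 and 0.19). EAF1, a subunit of the NuA4 acetyltransferase, rose by 1.90 ± 0.12, DOC1, of the anaphase-promoting complex, by 1.89 ± 0.15, and FOX2, an enzyme of peroxisomal fatty acid breakdown, by 1.88 ± 0.16. For these 8 limma's adjusted p lay between 1.39e-06 and 3.11e-05. The inactive fusion gave log2 0.22 to 0.58 at them, with limma's adjusted p at 0.998. The inactive fusion changed 0 of 4855 promoters by limma, with 148 under an unadjusted 0.05 (edgeR was not run there). Active exceeded inactive at 62 and lay below it at 1.

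**Figure D3:**
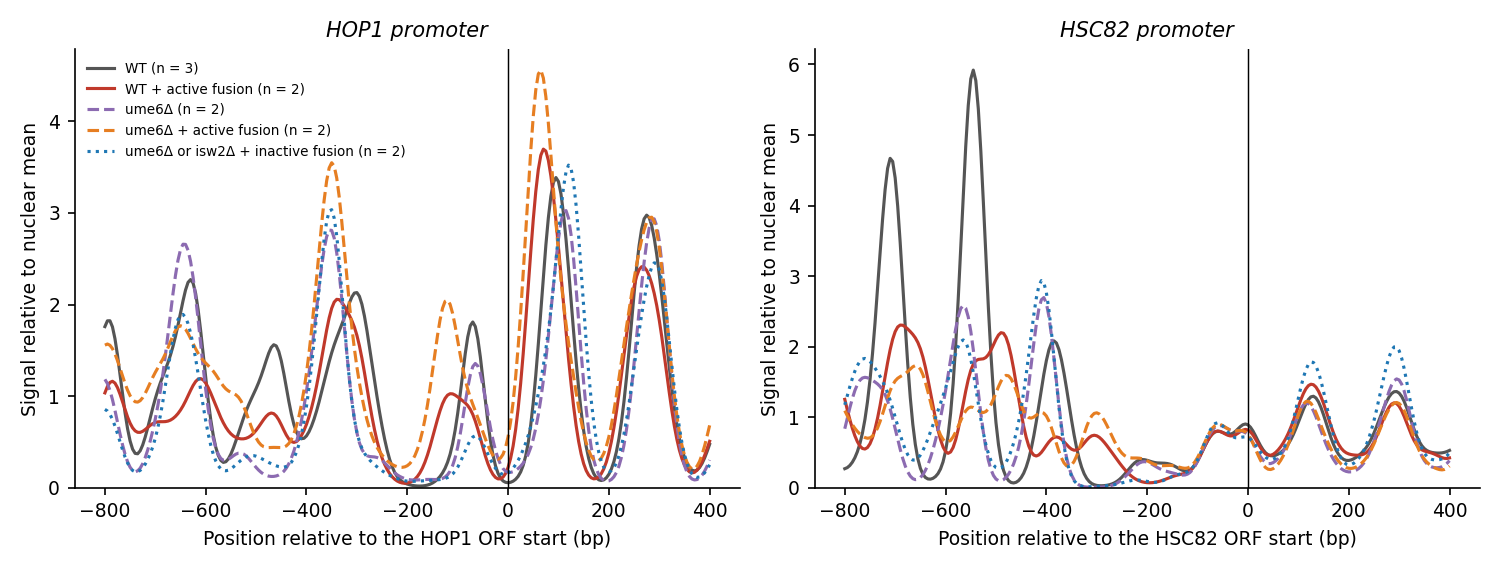
Smoothed nucleosome signal relative to the nuclear mean (vertical axes) against distance from the ORF start in bp (horizontal axes) at HOP1 (left) and HSC82 (right), as means of WT, WT with the active fusion, ume6 deletion, ume6 deletion with the active fusion, and the 2 inactive-fusion libraries. At HSC82 the trough in WT fills with the active fusion (log2 2.97 over all libraries), and the inactive fusion gave 0.25, which did not pass.

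Across 115647 windows of 100 bp, the active fusion raised 1466 and lowered 586, and 268 gains and 27 losses exceeded 2-fold. The largest gains away from the list sites lay between SNF2, the ATPase of the SWI/SNF remodeler, and YPK9 (XV 860501 to 860600, 5.58-fold, log2 2.48 ± 0.13 SE), and between POL31, a DNA polymerase subunit, and LSO1 (X 449001 to 449100, 5.39-fold, log2 2.43 ± 0.15). Others lay upstream of HSC82 (XIII 632001 to 632100, log2 2.33 ± 0.22), between PXA1, a peroxisomal fatty acid transporter, and PPT2 (XVI 273101 to 273200, log2 2.30 ± 0.22) and upstream of BMH2, a 14-3-3 protein (IV 652401 to 652500, log2 2.24 ± 0.20). The largest losses lay inside ORFs: ALP1, a basic amino acid transporter (XIV 135901 to 136000, log2 -1.29 ± 0.21), HSH155, a splicing factor (XIII 846001 to 846100, -1.29 ± 0.22), TVS1 (III 226001 to 226100, -1.28 ± 0.19), RTP1, the neighbour of HSC82 (XIII 631901 to 632000, -1.26 ± 0.22), and STP22, a sorting protein (III 106301 to 106400, -1.23 ± 0.22). Each of these 10 changed the same way in 5 of 5 matched differences, with limma's adjusted p between 7.06e-05 and 0.0205. Of the gains 21.8% lay within 600 bp upstream of an ORF, of the losses 10.8% and of all windows 15.2%, a description with no test of its own. Of those over 2-fold, 49.3% of the 268 gains and 22.2% of the 27 losses lay there. The total of 2052 was 1 without the 5 ume6-deletion libraries, which leaves 2 residual degrees of freedom in place of 6, and 275 without the 5 libraries whose high positions were set to 0. It was 619 without the matched sets as a block, 27 with 200 bp windows and 13275 with 50 bp windows. Quantile normalization gave 1123 gains and 838 losses. Leaving out WT replicate 1 or 3 gave 932 or 622 calls, ume6 replicate 1 619, ume6 with the active fusion replicate 1 or 2 1154 or 794, WT with the active fusion replicate 2 829, and isw2 with or without the active fusion 703 each.

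Between active and inactive fusion, 186 windows were higher and 42 lower with the active one, and 47.3% of the higher ones, 9.5% of the lower ones and 15.2% of all windows lay within 600 bp upstream of an ORF, again with no test of its own. Of those over 2-fold, 56.3% of the 142 higher and 22.2% of the 18 lower ones lay there. At the window between SNF2 and YPK9 the inactive fusion had a log2 change of 0.57 ± 0.19 SE, and at the HSC82 window 0.19 ± 0.31. The inactive fusion raised 3 windows and lowered 0 by limma, with 3724 under an unadjusted 0.05, and the 3 lay near URA3 or upstream of ADH1. Its count was 0 without either inactive library or ume6 replicate 1, 1 without WT replicate 3, isw2 with the active fusion, WT with the active fusion replicate 2 or either replicate of ume6 with the active fusion, and 13 without WT with the active fusion replicate 1. The total of 228 was 0 without either inactive library, 139 or 31 without WT replicate 1 or 3, and 4 without isw2 with the active fusion. It was 23 without ume6 replicate 1, 23 or 50 without ume6 with the active fusion replicate 1 or 2, and 774 or 36 without WT with the active fusion replicate 1 or 2. It was 16 without the block and 0 without the 5 ume6-deletion libraries. The limits of the inactive libraries given for the list sites hold here too.

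The isw2-deletion set, matched set 2, was used as libraries held out from the calls, a test chosen after the data were examined. Sets 1 and 3 alone called 420 windows gained and 69 lost with the active fusion, outside the regions near URA3 and ADH1 described in the closing section. Set 2 has 1 library per strain and so no replicate check. There the isw2 deletion with the active fusion exceeded its parent at 98.6% of the gained windows (median log2 1.05) and at 2.9% of the lost ones (median -0.88). Both medians lay outside those of all 10000 random lists matched on mean signal. The inactive fusion gave a median of 0.14 at the gained windows, also above all random lists, and -0.035 at the lost ones, inside them. Around 380 gained regions, mean signal within 25 bp of the centre was 0.815 in WT, 0.786 in the isw2 deletion, 0.863 with the inactive fusion and 1.5 with the active fusion. Around 103 bp to the side of loss it was 1.07, 1.06, 1.04 and 0.732. The median distance from the region centre to the nearest nucleosome maximum was 51 bp in WT, 54 bp in the isw2 deletion, 50.5 bp with the inactive fusion and 12.5 bp with the active fusion.

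**Figure D4:**
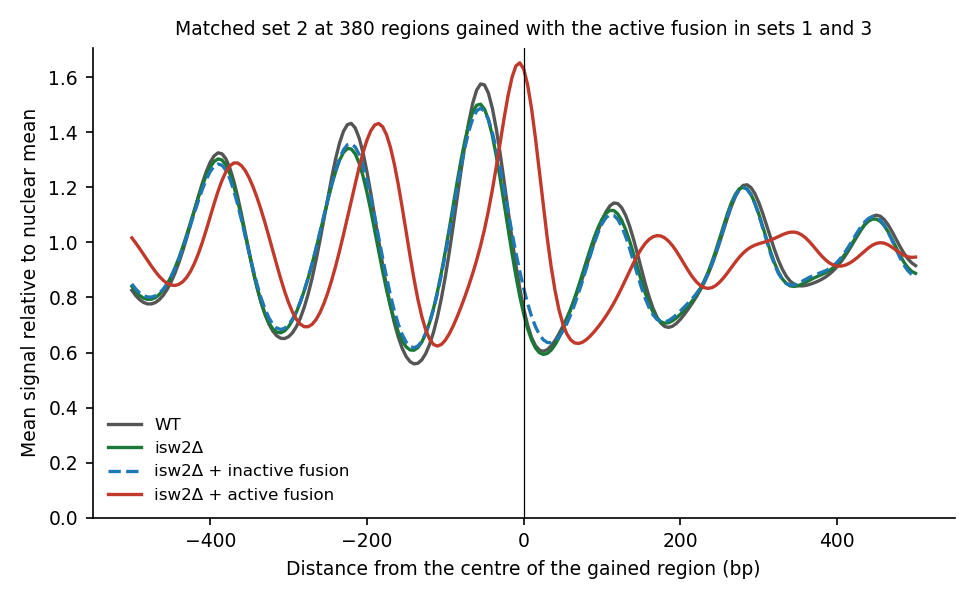
Mean signal relative to the nuclear mean (vertical axis) against distance in bp from the centre of 380 regions (horizontal axis) gained with the active fusion in matched sets 1 and 3, drawn for the 4 libraries of set 2, which took no part in choosing or turning them (side of loss to the right). Signal within 25 bp of the centre is 1.5 with the active fusion and 0.786 to 0.863 in the other 3 libraries, where the nearest maximum lies a median of 50.5 to 54 bp away.

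In WT cells, which keep their own Ume6, and in cells without it, the fusion raised signal at overlapping promoters. In WT 9 sites rose and 0 fell, led by HOP2 (log2 1.85 ± 0.25 SE), REC104 (1.32 ± 0.26) and CAR2 (1.30 ± 0.26). In the ume6 deletion 8 rose, among them SAE3 (1.23 ± 0.24), REC104 (1.21 ± 0.26) and HOP2 (1.08 ± 0.25), and 1 fell, ACS1, which makes acetyl-CoA (-0.70 ± 0.24), with limma's adjusted p over the list at or under 0.0494 in both. Adjusted over all promoters, 3 rose in WT, and 1, SAE3, in the ume6 deletion, where 0 fell. The difference between the backgrounds, tested itself by limma, passed at 0 of 49 sites (4 under an unadjusted 0.05, 0 by edgeR), with -0.78 ± 0.36 at HOP2 (adjusted p = 0.504). Across the 49 sites, which are not independent replicates, the effect in WT correlated with that in the ume6 deletion (Pearson r = 0.629, Spearman rho = 0.502) and in the isw2 deletion (r = 0.648, rho = 0.497), with no shared libraries. Over all 4855 promoters these were r = 0.277 and rho = 0.0477, with the same sign at 48.4%, and r = 0.378 and rho = 0.170. Quantile normalization over the 49 sites alone gave 5 rising and 6 falling in WT, 3 and 2 in the ume6 deletion, and 1 difference between them. Trough centres of all 13 libraries gave 2 rising in each. Without WT replicate 1 or 3, or WT with the active fusion replicate 1, the WT count was 4, 1 or 4. For the ume6 deletion it was 5 without either WT replicate or ume6 replicate 1, and 3 without ume6 with the active fusion replicate 2. The WT count was 5 by edgeR, 4 with a 10 bp centre, and 3 with a 75 bp centre, the genome mean alone or a pseudocount of 0.01. The ume6 count of 9 was 1 with a 10 bp centre or a pseudocount of 0.01, 3 with the genome mean alone, 4 with a pseudocount of 0.5 and 5 without the block. The test of the difference gave 1 site without ume6 or ume6 with the active fusion replicate 2, and 2 without WT with the active fusion replicate 2.

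Without Ume6, signal at 11 list promoters differed from WT when adjusted over the list alone. It rose at ACS1 (3.58-fold, log2 1.84 ± 0.24 SE) and SIP4, an activator of gluconeogenic genes (2.92-fold, 1.54 ± 0.24). Among early meiotic sites it rose at MEK1 (1.23 ± 0.25), HOP1 with SPO22 (1.03 ± 0.25), HOP2 (0.81 ± 0.25), REC8 (0.75 ± 0.26) and MND1 (0.69 ± 0.23), and at ITR1, an inositol transporter (0.69 ± 0.24). It fell at FAS2, a fatty acid synthase subunit (-0.88 ± 0.24), SMK1 (-0.74 ± 0.24) and ZIP2 (-0.73 ± 0.24). All 11 went the same way in both matched differences, with limma's adjusted p over the list at or under 0.0398 (2 libraries against their 2 matched WT). Adjusted over all 4855 promoters 2 passed, ACS1 and SIP4, and 0 on the early meiotic list by limma (8 under an unadjusted 0.05). HOP2 and the HOP1 and SPO22 site were shared with the 11 sites of the active fusion, 2 against 2.47 for independent lists. Against all promoters the metabolic list shifted upward (camera adjusted p = 0.036), with adjusted p = 0.391 when the correlation was estimated. Signal over chromosome XVI, which carries REC8, FAS2 and SMK1, was 1.70 ± 0.262 (SD, n = 5) of the median chromosome in the ume6-deletion libraries and 0.987 ± 0.00965 (SD, n = 8) in the others. The fixed pseudocount of 0.1 lowers a near-empty trough's value as the chromosome's signal rises. The falls at FAS2 and SMK1 cannot be told apart from this. On XVI, HSP82 (-0.31), GPH1 (-0.28), MEI5 (-0.21) and CAR1 (-0.18) also lay lower without passing, and REC8 alone rose. Sites were not refitted with each chromosome scaled to its own mean. Centres were troughs of WT, and placed on the trough of all 13 libraries 0 sites passed (9 under an unadjusted 0.05), with -0.11 at ACS1, -0.062 at MEK1, -0.24 at MND1 and -0.14 at ITR1. HOP2 gave -0.76 with a 75 bp centre and ZIP2 0.012 within 1000 bp. Quantile normalization over the list sites alone gave 5 rising and 4 falling, and edgeR 4 and 0. The count of 11 was 4 without WT replicate 1, 2 without WT replicate 3 and 4 without ume6 replicate 2.

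Of the 115647 windows, 26 were higher and 25 lower in the ume6 deletion than in WT. The windows with the largest gains all lay on chromosome XVI, inside DBF20 (747501 to 747600, log2 2.82 ± 0.25 SE), CSR2 (628101 to 628200, 2.39 ± 0.21), MMS1 (870901 to 871000, 2.19 ± 0.18) and YIG1 (170901 to 171000, 2.10 ± 0.19), and upstream of MMS1 (870501 to 870600, 2.19 ± 0.20). Lower windows lay upstream of CRC1, a carnitine carrier of mitochondria (XV 514401 to 514500, -2.67 ± 0.19), and between IGD1 and AIP5 (VI 182001 to 182100, -2.50 ± 0.23). Others lay between GPI12 and CAT8, an activator of gluconeogenic genes (XIII 832001 to 832100, -2.26 ± 0.15), between DHR2 and SMY1 (XI 288601 to 288700, -2.22 ± 0.19) and upstream of CAT2, a carnitine acetyltransferase (XIII 192701 to 192800, -2.05 ± 0.23). Limma's adjusted p was between 0.0275 and 0.0439 for these 10. Of the higher windows 21 of 26 lay on chromosome XVI, where the median of all windows was 0.63 against -0.097 elsewhere, and scaling each chromosome to its own mean gave 21 higher and 50 lower. The count of 51 was 0 without any 1 of WT replicate 1 or 3, ume6 replicate 2 or ume6 with the active fusion replicate 1 or 2, 8 without ume6 replicate 1, and 2863 without either replicate of WT with the active fusion. EdgeR gave 3302 higher and 255 lower, and with no filter on low signal 0 windows passed.

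The isw2 deletion was compared with its matched WT with 1 library each, so its values have no replicate check. Mean centre signal over the 49 list sites was 0.16 higher (log2) in the isw2 deletion than in WT, and 0.26 higher over the early meiotic sites. The centres are troughs of WT, this WT library included, which favours a higher value in any other strain. This comparison was not made at the trough of all 13 libraries, so these rises cannot be told apart from the choice of centres. The active fusion added 0.14 over the 49 sites and 0.18 over the early meiotic ones, and the inactive fusion -0.041 and -0.11. At HOP2 the isw2 deletion differed from WT by -0.42 and the active fusion from its parent by 2.10. At ACS1 these values were 0.39 and -0.037.

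**Figure D5:**
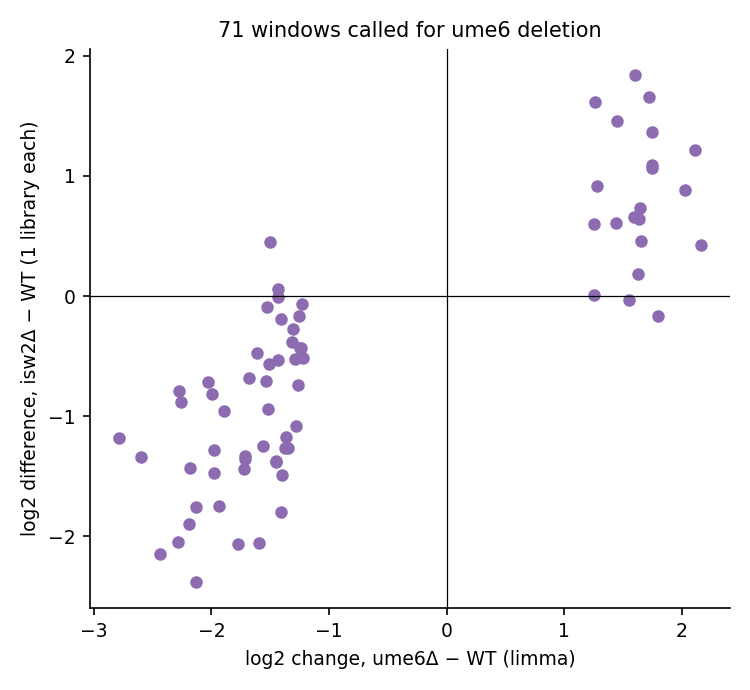
Log2 difference between the isw2 deletion and its matched WT (vertical axis, 1 library each) against the fitted log2 change in the ume6 deletion (horizontal axis, 2 libraries against 2 matched WT) at 71 windows called for the ume6 deletion after each chromosome was scaled to its own mean. Of the points, 67 have the same sign on both axes (94.4%).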

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

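The tests in this part were written after the values they concern were seen. No group holds 4 or more libraries, so no test asked whether a library stood apart from its group.

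Signal in the ume6-deletion libraries was uneven between chromosomes, a measure that no comparison used, and values are given where they exceed the highest library without the deletion by more than 0.1. Relative to the median chromosome, chromosome XVI held 1.58 in ume6 replicate 1, 1.91 in ume6 replicate 2, 1.73 and 1.96 in replicates 1 and 2 with the active fusion and 1.32 with the inactive fusion. Chromosome III held 1.96 in ume6 replicate 2, and chromosome IX held 2.00 in ume6 with the active fusion replicate 2 and 1.15 in ume6 replicate 1. Of 5 equal parts, the lowest of chromosome XVI held 0.944 of the whole chromosome's value, consistent with extra copies of the whole chromosome in part or all of the cells. Whether this follows from losing Ume6 cannot be told apart from a gain inherited by related strains, since the labels do not say how the strains were made (exact permutation p = 0.0333).

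Near URA3 and upstream of ADH1, regions whose limits were picked because windows there were called, signal was higher in the libraries with a fusion than in any without it. The mean at URA3 was 1.72 ± 0.266 (SD, n = 7) with a fusion and 0.982 ± 0.0818 (SD, n = 6) without, and upstream of ADH1 it was 1.52 ± 0.405 (SD, n = 7) and 0.724 ± 0.157 (SD, n = 6). Remodeling by the active fusion is argued against by the inactive-fusion libraries, the lower of which held 1.94 at URA3, above the highest library without a fusion, 1.06. Extra copies of DNA carried with the construct may account for it, since 7 of 7 fusion libraries lay above all others in both regions, but the construct is not described in the labels. All 3 windows called for the inactive fusion and 16 of those gained with the active fusion lay there.

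The fitted effect of the active fusion had opposite signs in WT and in the ume6 deletion at ACS1 and SIP4. At ACS1 the difference was -1.24 (0.54 in WT, -0.70 in the ume6 deletion) and at SIP4 -0.93 (0.30 and -0.63), opposite in every matched difference. The test of the difference by limma gave adjusted p = 0.063 and 0.287, so neither passed. The difference shares the ume6 and WT libraries with the comparison of ume6 with WT, so a rise measured there at a promoter lowers it.

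For the counts of the active fusion, 100 splits of the libraries within matched sets were compared, the real one included. Most of the others keep active libraries in both arms, so they are not free of the effect itself. Only 1 of 100 splits, the real one, gave as many windows (2052, highest other 397). This argues against chance as the whole source of that count but does not exclude it. For list sites 1 of 100 did (11, highest other 7), but centres at troughs of WT favour the real split, so that comparison cannot tell. With centres at the trough of all 13 libraries, 1 of 100 gave as many (5, highest other 3), which argues against chance as the whole source of those 5.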

How the results depend on the processing

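The alternatives chosen after the data were examined were edgeR, scaling within chromosomes, values as deposited, positions above 50 left out, all promoters, troughs of all 13 libraries, 1000 bp upstream for sites, leaving out chromosomes III, IX and XVI, the 5 ume6-deletion libraries or the 5 libraries with high positions set to 0. Added then too were every alternative for the windows of the inactive fusion, active against inactive, the fusion in each background and their difference, and window size and pseudocount for the ume6 windows. So were half-width, genome mean, pseudocount and filter for all list-site counts but that of the active fusion, quantile normalization for the sites of the inactive fusion, active against inactive and the difference, and the block and left-out libraries for gene lists and control places. Where a value below moved, the cause was not tested unless one is given. Motif scans with stricter, looser or control motifs, motifs in ORFs, distances of windows to motifs and the GC correction were not run for want of a genome sequence. Of the named genes, 18 list sites of the active fusion gave 486 values, of which 451 kept direction and side of the threshold, 26 lost the call, 5 gained it and 4 turned direction. The 11 ume6 sites gave 286 (196, 84, 0 and 6), the 10 windows of the active fusion 247 (213, 34, 0 and 0) and the 10 of the ume6 deletion 235 (152, 83, 0 and 0). In simulated counts, drawn without set effects or uneven chromosomes, 59.7% of 1.5-fold changes were found for the active fusion and 16.4% for the ume6 deletion.

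Windows of the active fusion (2052) numbered 13275 at 50 bp, 27 at 200 bp, 275 without the 5 libraries with high positions set to 0 and 1 without the 5 ume6-deletion libraries. The last leaves 2 residual degrees of freedom in place of 6. Windows of the ume6 deletion (51) numbered 896 at 50 bp, 1055 at 200 bp, 3 with pseudocount 0.01, 2317 with pseudocount 0.5 and 3557 by edgeR. With no filter on window signal 0 passed by limma, with 15633 under an unadjusted 0.05. Windows of the fusion in WT (13) numbered 84 scaled within each chromosome, 121 without chromosomes III, IX and XVI, and 225 without the 5 ume6-deletion libraries. Those of the fusion in ume6 (46) numbered 94 scaled within each chromosome and 97 without the 3 chromosomes. The inactive fusion (3) gave 5 without the 3 chromosomes. Without the 5 ume6-deletion libraries it gave 0 (1533 under an unadjusted 0.05 by limma), as did active against inactive (0, 4106 under 0.05).

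Without the matched sets as replicate block, windows numbered 619 for the active fusion, 2 for the ume6 deletion, 1 for the fusion in WT, 0 for the fusion in ume6 (limma, 2010 under an unadjusted 0.05), 16 for active against inactive and 1 for the inactive fusion. List sites without the block numbered 6 for the ume6 deletion and 5 for the fusion in ume6, and the distance difference was -7.93 bp (exact permutation p = 0.0598).

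All promoters in place of the list gave 173 calls for the active fusion, 63 for active against inactive, 18 for the ume6 deletion, 63 for the fusion in WT and 40 for the fusion in ume6, with more sites tested. Troughs of all 13 libraries gave 5, 3, 0 (limma, 9 under an unadjusted 0.05), 2 and 2 in the same order. A 10 bp centre gave 4 for active against inactive, 3 for the ume6 deletion, 4 for the fusion in WT and 1 for the fusion in ume6. A 75 bp centre gave 4 for the ume6 deletion and 3 for the fusion in WT. The genome mean alone gave 5 for the ume6 deletion, 3 for the fusion in WT and 3 for the fusion in ume6. Pseudocount 0.01 gave 3 for active against inactive, 4 for the ume6 deletion, 3 for the fusion in WT and 1 for the fusion in ume6, where pseudocount 0.5 gave 4. Quantile normalization over the list sites alone gave 5 for the fusion in ume6 and 1 for its difference from WT. EdgeR gave 4 for the ume6 deletion and 5 for the fusion in WT. Without the 5 ume6-deletion libraries there were 4 for active against inactive and 1 for the inactive fusion.

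The mean centre difference (0.22) was 0.18 at 75 bp (exact permutation p = 0.075), 0.053 over all promoters (p = 0.0625) and 0.25 without the 5 ume6-deletion libraries (p = 0.0625, the smallest those libraries allow). It was 0.12 at troughs of all 13 libraries (exact permutation p = 0.025), 0.091 with pseudocount 0.5 (p = 0.00833) and 0.44 with pseudocount 0.01 (p = 0.00417). At troughs of all 13 libraries the early meiotic difference (0.32) was 0.21 (exact permutation p = 0.0125), the metabolic one (0.10) 0.013 (p = 0.671) and the distance -6.25 bp (p = 0.158). The distance difference was -6.69 bp with peaks of at least 1 local mean (exact permutation p = 0.075) and -4.43 bp without the ume6-deletion libraries (p = 0.313). With 1000 bp upstream the active fusion gave -0.090 at MSH4, -0.11 at IME2 and -0.15 at HSP82, and the ume6 deletion 0.012 at ZIP2. At 75 bp CAR2 gave -0.012 for the active fusion and HOP2 -0.76 for the ume6 deletion. Troughs of all 13 libraries gave -0.11 at ACS1, -0.062 at MEK1, -0.24 at MND1 and -0.14 at ITR1 for the ume6 deletion.

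Leaving out each library in turn, a lone library being assumed to vary like the rest, gave 619 to 2335 windows for the active fusion, 0 to 2863 for the ume6 deletion, 0 to 10813 for the fusion in WT (10813 without WT with the active fusion replicate 2) and 0 to 68 for the fusion in ume6. It gave 0 to 774 for active against inactive, 0 to 13 for the inactive fusion and 0 to 2789 for the difference between backgrounds (2789 without WT with the active fusion replicate 2). List sites numbered 10 to 13 for the active fusion, 0 to 8 for active against inactive, 2 to 12 for the ume6 deletion, 1 to 10 for the fusion in WT, 3 to 11 for the fusion in ume6 and 0 to 2 for the difference. The inactive fusion gave 0 to 0 by limma. The mean centre difference ranged from 0.19 to 0.24, the distance from -9.58 to -6.40 bp (exact permutation p up to 0.0667), the early meiotic list from 0.29 to 0.35 and the metabolic list from 0.067 to 0.13 (exact permutation p = 0.0278 without ume6 replicate 1). The tRNA genes ranged from -0.094 to 0.080, ORF starts from -0.010 to 0.019 and ribosomal protein promoters from -0.11 to 0.14.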

Other observations

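The tests in this part were chosen after the data were examined. With each chromosome scaled to its own mean, 71 windows differed between the ume6 deletion and WT, 21 higher and 50 lower. Near CRC1 and CAT2, genes of carnitine transport and use, lower windows lay beside higher ones. Upstream of CRC1 the window at XV 514401 to 514500 was lower (log2 -2.60) and that at 514701 to 514800 higher (2.11). At CAT2 the window at XIII 192701 to 192800 was lower (-1.97) and that at 192801 to 192900 higher (1.44). In the isw2 deletion the same 4 windows differed from WT by -1.34, 1.22, -1.47 and 0.61, with 1 library each.

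A hypothesis is that losing Isw2 changes the same windows in the same direction as losing Ume6: the isw2 deletion, in another matched set whose libraries have weight 0 in the ume6 comparison, had the same sign at 67 of 71 windows (94.4%) against 60.6% of all windows (Pearson r = 0.836, Spearman rho = 0.809 across the 71, which are not independent replicates, 1 library against 1). Over all 115647 windows r was 0.290 and rho 0.294. Extra copies of chromosomes III, IX and XVI are argued against as the source by the windows outside them, where 44 of 47 (93.6%) had the same sign. The median difference over the 50 lower windows was -1.02, below all 10000 random lists matched on mean signal (lowest -0.26), which argues against windows of such signal varying between any libraries. Without Isw2 the active fusion may raise signal at the same 50 windows (median difference from the parent 0.56, highest random list 0.30, inactive fusion 0.056), but at the 21 higher windows (isw2 deletion 0.74) its median of -0.098 against the parent lay inside the random lists. Against the inactive fusion it was -0.20 there, at percentile 0.42 of the random lists (lowest -0.30). Effects of growth, or of a factor that both strains lack, remain open and were not tested.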
